A study of Mus musculus with 8 samples.

How the data were processed

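Liver stromal cells of 8 male C57BL/6 mice, per the labels, were measured by 10x Genomics single-cell RNA sequencing, 1 library per mouse. The labels give an age of 6 to 8 weeks and a control or an HFHC diet for 20 to 32 weeks. This age can thus not be that at the end of the diet. Dead cells were removed, and cells were stained for CD45, CD31, CD146 and PDPN and sorted. The deposited matrix holds raw UMI counts per gene and cell for 31053 genes, of which 17399 were detected. Per the labels, the authors processed the data with Cell Ranger 3.0.1 and Seurat on the mm10 build. The version of Seurat and the annotation release are not given in the sources used here. The 3416 deposited cells have at least 202 genes and at most 10% mitochondrial counts, so a filter at 200 genes and 20% removed none.

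Because 5 libraries shared many barcodes, each barcode was kept in the library where it had most UMIs, which left 3192 cells. This step was chosen after seeing the data. It removed 74, 42, 5 and 0 cells of the control libraries and 27, 34, 41 and 1 cells of the HFHC libraries. Kept libraries held 47 to 875 cells and 170448 to 2309209 UMIs.

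Counts were normalised to 10000 per cell and clustered with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15, with 2000 variable genes, 30 principal components, 15 neighbours and resolution 1. Clusters of at least 30 cells with markers of several classes were divided again, with 1000 genes, 10 components and resolution 0.5. A cluster took a class name where at least 3 markers fixed in advance were found in at least 10% of its cells at a log2 fold of at least 1, which gave 27 clusters in 15 classes and left 199 cells without a name. Such names describe transcripts, so classes are called LSEC-like and so on. Portal, arterial and central vein classes were joined as vascular endothelial-like cells. Gene positions came from GENCODE vM21 for mm10.

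Counts were summed per library and class with at least 10 cells and tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The intended test needed 3 libraries per diet, and only the sum of all cells met this. LSEC-like cells (3 control libraries, 1 HFHC) and vascular endothelial-like cells (2 control, 1 HFHC) were tested after seeing this. The SE beside an edgeR log2 fold change is the absolute change divided by the square root of the F statistic. It was derived from the test, and with 1 HFHC library it holds no spread among HFHC mice. LSEC-like cells of control 3 and HFHC 4, and other classes, were compared as a ratio of 1 control and 1 HFHC library of the same barcode-sharing set, with exact conditional 95% intervals and no test. Shares of cells were compared by a two-sided exact permutation test over 70 assignments, with adjustment over 15 classes, and single shares carry Wilson 95% intervals from scipy 1.17.1. A count of 0 allows up to 3 counts.

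The classes, markers, tests, lists and naming rule were fixed before the data were examined. In each main comparison, the named genes were the 10 largest rises and 10 largest falls among genes past the threshold, with at least 20 CPM in the higher group and no overlap between the groups. Mitochondrial, ribosomal, immunoglobulin, haemoglobin, sex-linked and predicted genes, marker genes and transcripts of other cell types were left out of these. Up to 4 members of each list with the smallest adjusted p, and 14 endothelial genes fixed in advance, could be named besides, and for all cells summed 3 rises and 3 falls, or the 5 smallest p. Some single genes are not reported here. Of 36 gene lists fixed in advance, those with at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, prior count 2), and again with an estimated correlation and with fry. In the ratios of single libraries, list medians were ranked among 10000 random lists of like expression.

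On simulated counts of the LSEC layout, with 200 changed genes among 7040, edgeR recovered 2% of 2-fold, 40% of 4-fold, 72% of 8-fold and 78% of 32-fold changes, with 11 false calls among 107. For vascular endothelial-like cells it recovered 6, 34, 60 and 72% (8 false of 94), and for all cells summed 0, 6, 32 and 86% (7 false of 69). About 10% of the calls were thus false in simulation, above the 5% aimed at. The 32-fold size was added after a first simulation recovered few changes.

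Alternatives were DESeq2 1.42.0 or its size factors, no filter on low counts, at least 500 genes or under 10% mitochondrial counts per cell, removal of the 46 cells that Scrublet called doublets, resolution 2, clustering centred per sample, classes from marker expression, minima of 5 and 20 cells, a replicate block and leaving out each library. Keeping barcode copies, and library sets, were added after seeing the data. Sequence reads were not used here.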

Results

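Single-cell RNA sequencing measured the transcripts of liver stromal cells from 8 mice, 4 fed a control diet and 4 fed a high fat, high cholesterol (HFHC) diet for 20 to 32 weeks. The design text names the diet so, while the titles of the HFHC samples say calorie in place of cholesterol. The cells had been sorted to enrich endothelial cells. Each mouse gave 1 library, and 3192 cells were kept over the 8 libraries. The control libraries 1 to 4 held 55, 875, 574 and 94 cells with 170448, 1775987, 836008 and 257355 unique molecular identifiers (UMIs). HFHC libraries 1 to 4 held 47, 74, 857 and 616 cells with 304090, 317319, 2309209 and 1078909 UMIs. The median UMI count per cell ran from 1364 in control 2 to 5928 in HFHC 1. Intervals, and the upper limits beside counts of 0, cover counting error only.

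The same cell barcodes occurred in several libraries. Control 1, control 2, HFHC 1, HFHC 2 and HFHC 3 shared 33 to 65 barcodes in each pair, and all other pairs shared at most 4. These 5 libraries are called the barcode-sharing libraries, and control 3, control 4 and HFHC 4 the other 3 libraries. A shared barcode was kept only in the library with most of its UMIs, which removed 224 of 3416 cells.

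The first comparison asked which kinds of cell each diet group held. Liver sinusoidal endothelial cell (LSEC)-like cells, which line the liver capillaries, made up most of 2 libraries, with 540 of 574 cells in control 3 (94.1%, Wilson 95% interval 91.8 to 95.7) and 496 of 616 in HFHC 4 (80.5%, 77.2 to 83.5). Hepatocyte-like barcodes made up most of 2 others, with 563 of 875 cells in control 2 and 618 of 857 in HFHC 3. Kupffer-like cells, named for the resident liver macrophages, were found in HFHC 1 (10 of 47 cells) and HFHC 2 (15 of 74). Their cluster had the Kupffer markers Clec4f, Cd5l, C1qa, C1qb and Adgre1, while Vsig4 and Timd4 did not pass as its markers. Ms4a7, Il12b, Mmp12, Trem2 and Tnf were among its leading genes, and it also carried markers of cholangiocytes. Cholangiocyte-like cells, which line bile ducts, made up 27.7% (16.9 to 41.8) of HFHC 1 and 48.6% (37.6 to 59.8) of HFHC 2. Vascular endothelial-like cells, of portal, arterial and central veins, made up 15.4% of HFHC 4, 4.26% of control 4 (4 of 94 cells) and 3.89% of control 2.

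No class passed the test between the diets, and with 4 libraries per diet the exact test gives no raw p below 0.0286 and, for 1 class among 15, no adjusted p below 0.429. LSEC-like cells averaged 36.6% ± 41.3 (SD, n = 4) of control and 20.5% ± 40 (SD, n = 4) of HFHC cells, with p = 0.457 in the two-sided exact permutation test. Kupffer-like cells averaged 0% of control and 10.4% ± 12 (SD, n = 4) of HFHC cells (exact p = 0.429). These classes depended on the clustering, since clustering centred per sample put 23 of 55 cells of control 1 among Kupffer-like cells, against 17 of 47 in HFHC 1 and 22 of 74 in HFHC 2. Classes from marker expression put 3, 1, 7 and 1 Kupffer-like cells in controls 1 to 4 and 15, 17, 6 and 7 in HFHC 1 to 4, a difference of 12.2 points (exact p = 0.286). The cluster named monocyte or macrophage-like, with 1, 6 and 1 cells of controls 1 to 3, was led by Cd5l and Vsig4 among others, which Kupffer cells carry. The Kupffer-like difference was 13.8 points within the barcode-sharing libraries, 0 within the other 3 and 6.76 without HFHC 1. Without Scrublet doublets it was 8.59, with 5 Kupffer-like cells left in HFHC 1. The smallest raw p of the 15 classes was 0.143, for monocyte or macrophage-like cells at 0.67% and 3.51% (exact test, n = 4 per group), and the adjusted p was 1 for each class. Its difference of 2.84 points was 0.571 with clustering centred per sample, 0.838 with barcode copies kept, 1.54 with classes from marker expression and 3.96 without HFHC 4, with unadjusted exact p of 0.714, 0.286, 0.257 and 0.0286. The difference for LSEC-like cells, −16.1 points over all libraries, was −5.97 within the barcode-sharing libraries and 13.8 within the other 3, and leaving out control 3 also turned it, to 3.08. It was −6.01 with classes from marker expression and −7.86 as percent of endothelial-like cells. For vascular endothelial-like cells the difference of 1.46 points was −1.67 and 12.2 within these sets and −2.33 without HFHC 4. It was −1.80 with classes from marker expression and 17.0 as percent of endothelial-like cells. For both classes that percent leaves out HFHC 1, which had 0 endothelial-like cells. It rests on 4 such cells in control 1, 1 in HFHC 2 and 10 in HFHC 3. The sort gates set these shares in part.

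**Figure D1:**
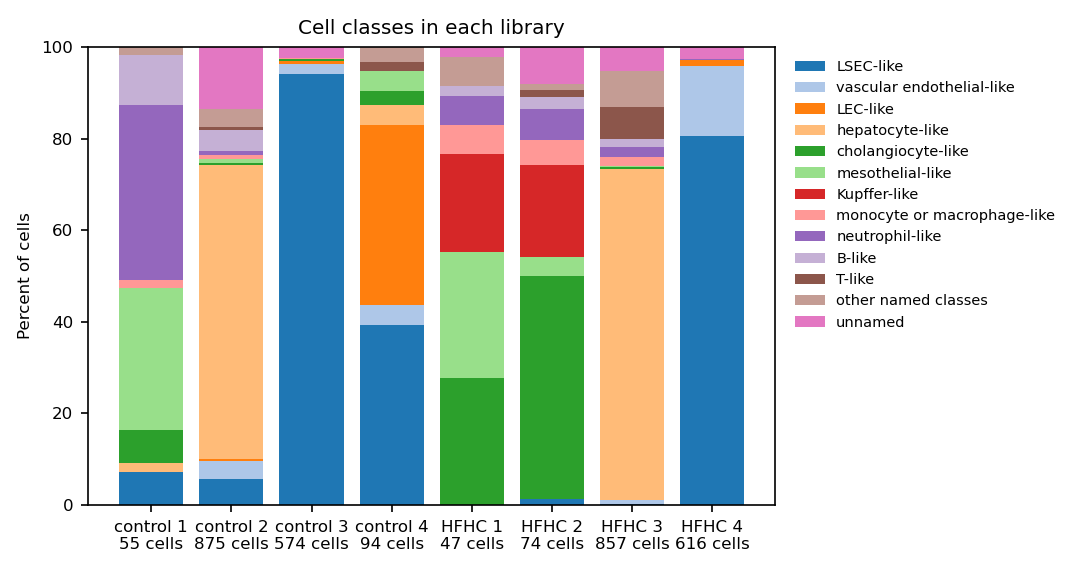
Percent of cells in each class, 1 stacked bar per library with its number of cells. LSEC-like cells fill 94.1% of control 3 and 80.5% of HFHC 4, and hepatocyte-like barcodes 64.3% of control 2 and 72.1% of HFHC 3.

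The series title names the liver lymphatic system, so lymphatic endothelial cells (LEC) were looked for in every library. They were found in number in control 4 alone, where 44 of 94 cells (46.8%, Wilson 95% interval 37.1 to 56.8) carried at least 2 of 6 lymphatic markers. Next came HFHC 2 with 5 of 74 cells, which are not shown to be LEC, since the library had Pdpn in 20 cells, Prox1 in 7, Mmrn1 in 1 and Ccl21a in 0, and none of its cells in the LEC-like cluster. HFHC 4 had 0 of 616, which allows up to 0.487% of cells with 2 markers detected and does not count LEC whose markers were missed. The LEC-like cluster held 37 cells of control 4, 33 of them with at least 2 markers. It held 7 cells of HFHC 4, 3 each of control 2 and control 3 and 1 of HFHC 3, none of which carried 2 markers. In LSEC-like cells of control 4, which should lack these transcripts, 5 of 37 carried at least 2 markers and 23 of 37 had Ccl21a. The mean share of LEC-like cells was 10.1% ± 19.5 (SD, n = 4) in control and 0.313% ± 0.551 (SD, n = 4) in HFHC libraries, with an exact permutation p of 0.543, and the difference of −9.74 points became 0.0248 without control 4. Within the sets the difference was −0.133 and −18.8 points. With LEC-like cells in a single library, the effect of the diet on LEC-like cells, and how it differs from that on LSEC-like cells, were not tested.

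Within control 4, the 37 LEC-like cells could be set beside 37 LSEC-like cells of the same animal, over 120604 and 76644 UMIs. Ccl21a, Mmrn1 and Prox1 are among the markers that gave the LEC-like cluster its name, so their excess there was built in. Ccl21a, the chemokine with which lymphatic vessels attract leukocytes (chromosome 4, 42772860 to 42773993, mm10), was 65.8 times as abundant in LEC-like cells (counting interval 50.1 to 88.2), and Mmrn1, a secreted lymphatic endothelial protein, 46.1 times (17.8 to 170). Lyve1, the hyaluronan receptor that both cell types carry, was 8.54 times as abundant (5.89 to 12.8), and Cldn5, a tight junction protein, 3.08 times (2.47 to 3.88). Icam1, an adhesion receptor for leukocytes, had 24 counts against 1 (ratio 15.3, 2.49 to 627). Prox1, the transcription factor of lymphatic identity, stood at 315 CPM (counts scaled to the total of the class) against 0, which allows up to 39.1 CPM. The LEC to LSEC ratio was below 1 for Cd36, a receptor for fatty acids and oxidised lipoproteins (0.227, 0.0984 to 0.481), for Cdh5 of the adherens junction (0.311, 0.183 to 0.517) and for the growth factor receptors Nrp2 (0.482, 0.264 to 0.869) and Flt4 (0.583, 0.352 to 0.961). The interval for Klf2, a transcription factor induced by blood flow, included 1 (1.30, 0.943 to 1.82). Olr1, the oxidised LDL receptor, and the lymphatic growth factor Vegfc had 0 counts in both cell types, which allows up to 24.9 CPM in LEC-like and 39.1 in LSEC-like cells. These ratios come from 1 animal and have no replicate check.

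Control 4 also differed from its label in sex-linked transcripts. The labels describe male mice, but Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254, mm10), was found in 67 of its 94 cells (71.3%), and Y-linked transcripts in 0, which allows up to 3.19%. The share with Xist was 78.4% in its LSEC-like and 75.7% in its LEC-like cells. In the 7 other libraries Xist was found in 0 cells, and Y-linked transcripts in 18.0 to 53.2%.

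**Figure D2:**
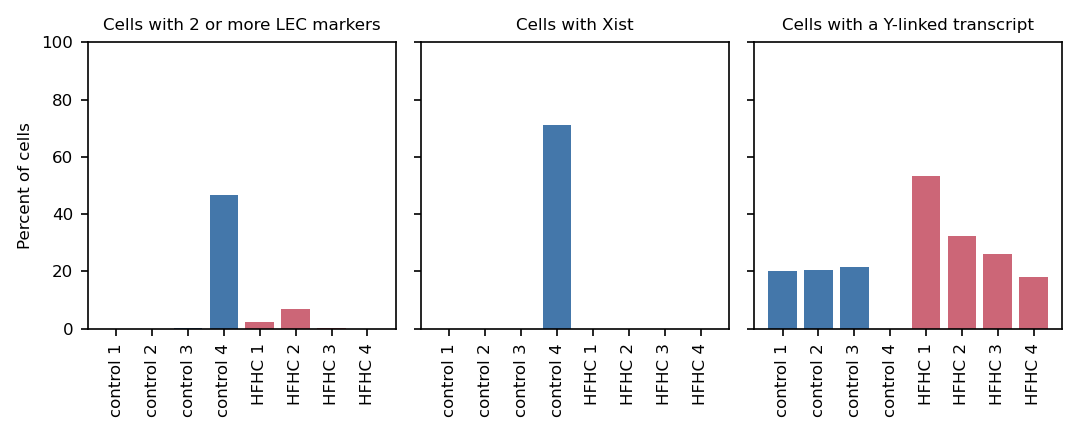
Percent of cells of each library with at least 2 lymphatic markers, with Xist and with a Y-linked transcript. Control 4 stands at 46.8% for lymphatic markers, 71.3% for Xist and 0% for Y-linked transcripts.

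The main endothelial comparison set LSEC-like cells of HFHC 4 against the controls. HFHC 4 was the only HFHC library with at least 10 of them, so the comparison describes that library and not the HFHC group. An LSEC-like cluster with Esm1, Cxcl9, Kcnj8, Cd36, Kcne3 and Abcc9 among its leading genes held 208 of the 496 cells of HFHC 4. It held 26 of 540 in control 3, 4 of 50 in control 2 and 0 of 37 in control 4. The summed counts mix this cluster with the others, so a shift in its share was not told apart from a change within cells. In HFHC 4, Esm1, Kcnj8, Abcc9, Kcne3, Cd36, Fabp5 and Abca1 were among 13 genes that rose against the controls 2, 3 and 4, and Plpp1, Cyp26b1 and Wnt2 among 6 that fell. Esm1, a proteoglycan secreted by activated endothelium (chromosome 13, 113209659 to 113218098, mm10), rose with the smallest adjusted p, from 4.59 ± 4.92 CPM (SD, n = 3) to 524 CPM, a log2 fold change of 6.98 (SE 0.61, edgeR adjusted p = 1.46e-15). Kcnj8 (3.87, SE 0.72) and Abcc9 (3.73, SE 0.82), neighbours on chromosome 6 that encode the pore and the regulatory subunit of a vascular ATP-sensitive potassium channel, rose with Kcne3 (5.10, SE 0.87), a potassium channel accessory subunit. Kcne3 had 3 counts in control 3 and 0 in the other controls. Its ratio of HFHC 4 to control 3 was 25.9 (counting interval 8.56 to 128). Kcnj8 had 10 counts in control 3, and over 15 settings its log2 fold change ran from 3.64 to 8.47. Cd36, a receptor for fatty acids and oxidised lipoproteins (chromosome 5, 17781690 to 17888801), rose from 350 ± 206 CPM (SD, n = 3) to 1291 CPM (log2 1.99, SE 0.42, edgeR adjusted p = 0.0320). Fabp5, a fatty acid-binding protein, rose by 1.77 (SE 0.37), and Abca1, the cholesterol efflux transporter (chromosome 4, 53030787 to 53159895), by 2.86 (SE 0.70). Over 14 settings the log2 fold change of Abca1 ran from 1.81 to 8.19, and it passed in 7.

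Of 7040 genes tested with edgeR in LSEC-like cells, 13 rose and 6 fell. Gpx3, a secreted glutathione peroxidase, had 0 counts in the 3 controls and 34 in HFHC 4, at least 12.6-fold higher against a limit of 3 counts over the control group. Cd34 (3.35), Galnt15 (3.76), the lysosomal membrane protein Cd63 (2.15) and the interferon-induced chemokine Cxcl9 (1.77) rose as well. The last riser was 8430408G22Rik (5.56), named after its values were seen because the naming rule leaves out predicted genes. Plpp1, a lipid phosphatase and the most abundant of the genes that fell, went from 1832 ± 98.6 CPM (SD, n = 3) to 454 CPM (log2 −1.81, SE 0.44). Cyp26b1, which breaks down retinoic acid, fell by 2.27 (SE 0.52) on the log2 scale, and Wnt2, a Wnt ligand of endothelium near the central vein, fell by 1.92 (SE 0.46). Hpgd, which degrades prostaglandins, fell by 1.86 (SE 0.46), Slco2a1, which takes them up, fell by 2.25 (SE 0.54), and adenosine deaminase, Ada, fell by 2.69 (SE 0.65). Each of the 19 genes lay in HFHC 4 above or below all 3 controls.

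Among the genes chosen in advance and reported here in LSEC-like cells, 2 rose (Cd36 and Abca1) and 8 did not pass. Klf2 stood at −1.34 (SE 0.43, edgeR adjusted p = 0.273), Lyve1 at −0.48, Flt4 at −0.28, Nrp2 at −0.13, Cdh5 at −0.15, Cldn5 at −0.20, Icam1 at 0.51 and Vcam1 at 0.28 on the log2 scale, the last 7 with adjusted p of at least 0.999. Olr1 (0 counts in the 3 controls, 2 in HFHC 4) and Vegfc (4 and 11) were too sparse to test.

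The LSEC test rests on 3 control libraries and 1 HFHC library, in place of the intended 3 per group, and takes HFHC 4 to vary as the controls do, while control 2 set alone against the other 3 libraries called 13 genes. The title of HFHC 4 numbers its animal 14 where the other HFHC titles run from 1 to 3, so its place in the group rests on its description. DESeq2 called 3 genes, 1 higher and 2 lower, against a raw p under 0.05 for 151 genes with DESeq2 and 284 with edgeR. DESeq2 size factors in edgeR gave 16 higher and 21 lower. Without control 2 the test used the other 3 libraries alone and called 6 genes, Esm1, 8430408G22Rik, Kcne3 and Kcnj8 again higher, Cyp26b1 again lower, and Odc1 (edgeR adjusted p = 0.00461) added. Without control 4, the library with Xist, 65 genes passed, among them all 19.

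**Figure D3:**
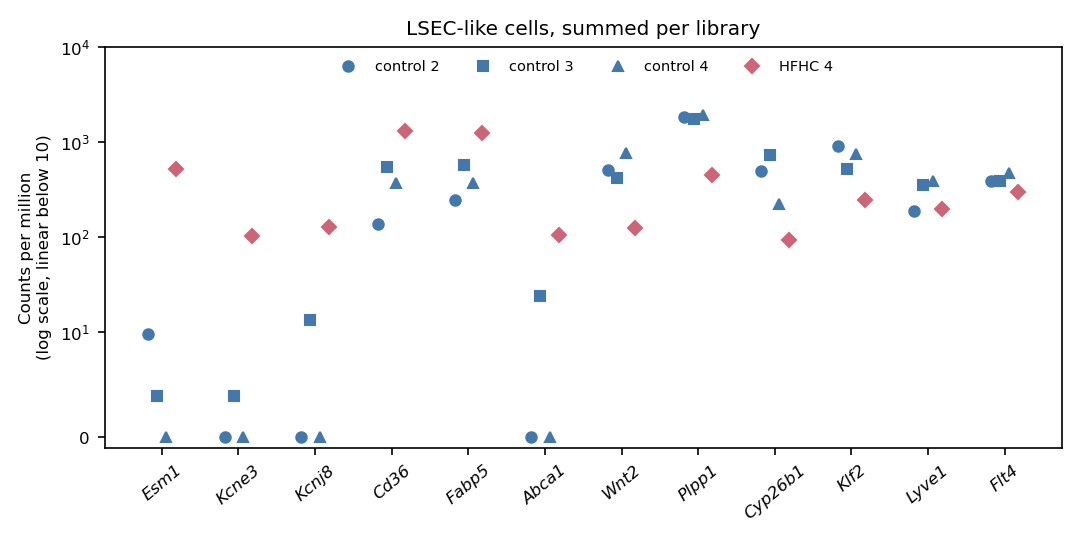
CPM of 12 genes in LSEC-like cells summed per library, on a log axis that is linear below 10, with 3 control libraries as blue symbols and HFHC 4 as red diamonds. HFHC 4 lies above all controls for Esm1 (524 CPM) and Cd36 (1291 CPM) and below them for Wnt2 (124 CPM) and Plpp1 (454 CPM).

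Gene lists fixed in advance included markers of zones of the sinusoid. Of 16 measured pericentral endothelial genes, 14 were lower in HFHC 4 (median log2 −1.57), among them Wnt2, the sole member that fell over all genes tested, with Kit at −1.83 (edgeR adjusted p = 0.0974). Pcdh17 (1.44) and Fabp4 (1.09) were the 2 higher members, and 2 rose and 5 fell adjusted over the list alone. Of 16 periportal endothelial genes, 15 were higher (median 0.58), with Galnt15 past the test and Ntn4 (1.61), Efnb2 (1.55) and Ly6c1 (2.58) not past it. 1 rose over all genes tested and 3 adjusted over the list alone. Of 18 genes of sinusoidal specialisation, 15 were lower (median −0.52), 2 fell (Wnt2 and Plpp1) and 4 fell adjusted over the list alone. The camera test gave adjusted p = 1.81e-08 for the pericentral, 1.43e-05 for the periportal and 4.08e-07 for the sinusoidal list, and adjusted p = 0.682 with an estimated correlation for each of the 3.

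Metabolic lists went both ways. Of 11 cholesterol biosynthesis genes in LSEC-like cells 10 were lower (median −0.62), of 16 NRF2 and antioxidant genes 14 were lower (−0.32), and of 13 mitochondrially encoded genes all 13 were lower (−0.84). No member of these lists passed, over all genes or adjusted over the list alone. Their camera adjusted p values were 0.00234, 0.00697 and 0.00697, and adjusted p = 0.682, 0.706 and 0.706 with an estimated correlation. Control 2 stood high in mitochondrially encoded genes, with mt-Nd4 at 5590 CPM against 1678 and 2179 in controls 3 and 4 and 1547 in HFHC 4, and without control 2 the median of this list was −0.06 (camera adjusted p = 0.576). The NRF2 list did not pass without control 2 or control 3 either (camera adjusted p = 0.236 and 0.124). Glycolysis and hypoxia genes were higher for 16 of 18 members (median 0.33, camera adjusted p = 0.0822, or 0.0162 without control 2) and nuclear encoded oxidative phosphorylation genes for 28 of 37 (0.23, camera adjusted p = 0.163), with 0 members past the test. Shear stress genes, with Klf2 and Thbd (−1.57), had 9 of 12 members lower (median −0.35, camera adjusted p = 0.0488, adjusted p = 0.706 with an estimated correlation), 0 past over all genes and 1 fallen adjusted over the list alone, and this list did not pass without control 2 or control 4 (camera adjusted p = 0.364 and 0.0790). Transcripts of other cells moved with them. Hepatocyte transcripts were lower for 16 of 17 genes (median −2.49, camera adjusted p = 4.08e-07, adjusted p = 0.682 with an estimated correlation), and control 2, the library rich in hepatocyte-like barcodes, had the highest level of 16 of the 17, such as Serpina1c at 206 CPM against 14.5 in control 3. Kupffer transcripts were lower for 5 of 5 and stellate transcripts for 3 of 3 genes (camera adjusted p = 0.000501 and 0.000503, adjusted p = 0.682 with an estimated correlation for both), and the Kupffer list did not pass without control 3 or control 4 (camera adjusted p = 0.141 and 0.275). In all, 10 of 33 lists passed camera, and 0 passed with an estimated correlation or with fry.

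Lists closest to the series title did not pass in LSEC-like cells with all 3 controls. For the lipoprotein uptake and leukocyte adhesion lists, passing camera depended on which control was left out. Their medians stayed above 0 throughout, at log2 0.44 to 0.90 and 0.27 to 0.50. Of 16 oxidised LDL and scavenger receptor genes 8 were measured, 1 rose (Cd36, also the count adjusted over the list alone), and the median was −0.21 against a mean of 0.05 (camera adjusted p = 0.780). Lipoprotein and fatty acid uptake genes had 7 of 9 members higher, with 1 risen over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0822). LXR targets, which respond to cholesterol, had 8 of 11 higher with Abca1 risen (0.163). Of 21 lymphatic endothelial function genes 0 passed over all genes and 1 fell adjusted over the list alone (0.828). Leukocyte adhesion and chemokine genes had 10 of 14 higher with Cxcl9 risen (0.0601).

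Control 3 and HFHC 4, with 540 and 496 LSEC-like cells, were the 2 libraries with most of them and shared few barcodes with any other. In this pair the pericentral list had a median log2 ratio of −1.11 and the sinusoidal list −0.80, with 17 of 18 members lower, both below all 10000 random lists of like expression. The periportal list had 10 members higher and 6 lower, with a median of 0.12 (percentile 98.4). Higher medians were seen for LXR targets (0.48, percentile 99.9), leukocyte adhesion (0.25, 99.5) and lipoprotein uptake (0.48, 98.0). Medians were negative for scavenger receptors (−0.41, percentile 4.47) and lymphatic function (−0.27, 10.3). Plpp1 stood at a ratio of 0.262 (counting interval 0.233 to 0.293), Wnt2 at 0.301 (0.239 to 0.377), Cyp26b1 at 0.128 (0.0993 to 0.162) and Esm1 at 132 (44.9 to 643). The hepatocyte median was −0.61 and the mitochondrial median 0.01 in this pair. Immediate early genes, which rise when tissue is dissociated, were higher for 12 of 15 members (median 0.59, above all random lists), for instance Jun at 2.98 (2.16 to 4.20). This pair compares libraries, not diets, and has no replicate check.

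Vascular endothelial-like cells of HFHC 4 (95 cells) could be set against those of controls 2 and 3 (34 and 13 cells), which describes that library and not the HFHC group. In HFHC 4, Igfbp5, which binds insulin-like growth factors, rose from 84.8 ± 18.5 CPM (SD, n = 2) to 556 CPM (log2 2.79, SE 0.56, edgeR adjusted p = 0.000258). Ctla2a, a protease inhibitor, rose by 2.18 (SE 0.52), and Lrg1, a secreted glycoprotein of vessel growth, by 1.91 (SE 0.48). In controls 2 and 3, Igfbp5 had 8 and 3 counts, Ctla2a 17 and 2, and Lrg1 24 and 4. The class joins a portal or arterial and a central vein cluster, with 24 and 10 cells in control 2. These clusters held 12 and 1 cells in control 3 and 72 and 23 in HFHC 4. A shift in this mix was not told apart from a change within cells. Of the 17 genes that fell, 13 were at least 5 times as abundant in the hepatocyte-like barcodes of control 2 as in its vascular cells, among them Serpina1e (at least 12.6-fold lower against 3 counts over the group), Gsta3 (at least 10.1-fold) and Gnmt (at least 9.72-fold). The other 4 were the immunoglobulin gene Igkc, the haemoglobin gene Hbb-bs, Cyp1a1, a detoxifying enzyme (at least 9.72-fold lower), and S100a6, a calcium-binding protein, which fell by 3.81 (SE 0.76). Control 3 held at most 2 counts of any of the 17, so their control level came from control 2, which had 57 counts of S100a6 against 1 in control 3 and 4 in HFHC 4.

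Hepatocyte transcripts in vascular endothelial-like cells were lower for 13 of 13 genes. Of these 7 fell over all 2516 genes tested and 12 adjusted over the list alone (camera adjusted p = 4.08e-07, adjusted p = 0.958 with an estimated correlation). Mitochondrially encoded genes were lower for 13 of 13, with 0 fallen over all genes and 8 adjusted over the list alone (camera adjusted p = 0.00181, adjusted p = 0.958 with an estimated correlation). Control 2 stood high here too, with mt-Cytb at 7474 CPM against 1861 in control 3 and 1743 in HFHC 4. Pericentral endothelial genes were higher for 7 of 10 members (median log2 0.35), with Wnt2 at 1.02. This is opposite in direction to the LSEC-like cells of HFHC 4, where 14 of 16 were lower. Among genes chosen in advance Klf2 (−0.83), Cd36 (−0.52), Vcam1 (−0.99), Icam1 (0.91), Abca1 (2.27), Flt4 (0.70) and Nrp2 (0.66) did not pass, each at an edgeR adjusted p of 0.999. DESeq2 called 0 genes, with a raw p under 0.05 for 10, where edgeR had 99, and edgeR called 0 on classes from marker expression (raw 31) and 0 with a minimum of 5 cells (raw 23), which adds HFHC 3 with 7 cells. The lone HFHC library is taken to vary as the 2 controls do, which leaves 1 residual degree of freedom and a spread borrowed across genes.

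All cells of a library summed allowed 4 libraries per diet but mix composition with expression. Plscr1, a phospholipid scramblase induced by interferon, had the smallest p, at 22.2 ± 9.72 CPM (SD, n = 4) in control and 273 ± 264 (SD, n = 4) in HFHC (log2 3.42, SE 0.95, edgeR adjusted p = 0.999). Inafm2 (−1.29), Tmem106c (1.41), Bcl2 (1.67), which blocks apoptosis, and Chmp7 (1.32) followed, none past the test. Of 6666 genes 0 passed with edgeR (54 at raw p under 0.05) and 0 with DESeq2 (126). Genes of sinusoidal specialisation were lower for 18 of 18 members (median −1.31, camera adjusted p = 1.91e-15), Kupffer transcripts higher for 10 of 11 (median 2.75, camera adjusted p = 6.32e-05), and leukocyte adhesion and chemokine genes higher for 16 of 17 (median 1.41, camera adjusted p = 1.53e-06). These went with the unequal shares of LSEC-like and Kupffer-like cells, and of the 18 lists past camera 0 passed with an estimated correlation (adjusted p = 0.443 to 0.653). Within the barcode-sharing libraries edgeR called 0 genes and within the other 3 libraries 1.

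Of the other classes, hepatocyte-like barcodes were the most numerous, in control 2 (563) and HFHC 3 (618), over 959028 and 1519970 UMIs. Metallothionein and acute phase genes were higher in HFHC 3 for 8 of 8 members (median log2 ratio 1.94), with the metal-binding Mt2 at 12.3 times and, among proteins the liver secretes in inflammation, Saa2 at 15.4 times (counting interval 7.65 to 36.1) and Saa1 at 9.32 times (5.32 to 17.8). Interferon response genes were higher for 10 of 10 (median 1.35), such as Isg15 at 2.77 times (2.05 to 3.79). Cholesterol biosynthesis genes were lower for 12 of 12 (median −1.03), such as Idi1 at 0.196 (0.155 to 0.247) and Hmgcs1 at 0.486 (0.413 to 0.571), and genes of the unfolded protein response for 9 of 10 (median −0.98). Each of these 4 medians lay outside all 10000 random lists. The same held for hepatocyte transcripts (lower for 19 of 25, median −0.38) and lymphocyte transcripts (lower for 2 of 3, median −3.93). It also held for red cell and mitochondrially encoded transcripts, so the rank does not set the 4 lists apart. Plin2, which coats lipid droplets, stood at 2.74 times (2.48 to 3.03), and the major urinary protein Mup7 at 0.0686 (0.0547 to 0.0850).

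The barcodes themselves differed between these libraries. Mitochondrially encoded transcripts took a median of 4.84% of counts in control 2 and 0.0351% in HFHC 3, where they were lower for 13 of 13 genes (median log2 ratio −6.04). B-like cells of the same libraries stood at 7.98% and 3.16%. Red cell transcripts were lower in HFHC 3 for 5 of 5 genes (−1.61). The hepatocyte-like barcodes of the 2 libraries fell mostly into different clusters, the largest with 6 of control 2 and 532 of HFHC 3. These ratios compare libraries, not diets, and have no replicate check.

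**Figure D4:**
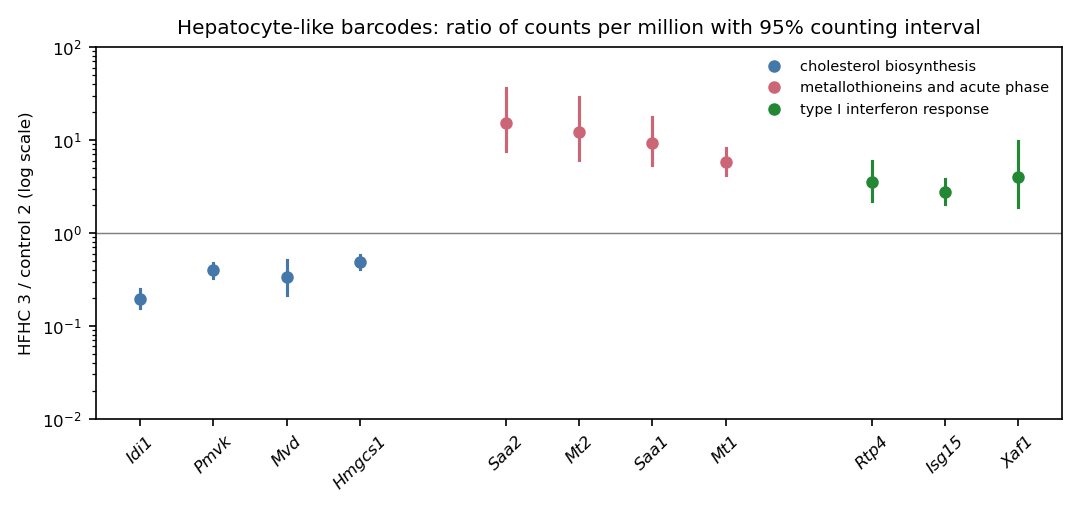
Ratio of CPM in hepatocyte-like barcodes of HFHC 3 to control 2, on a log axis, with 95% counting intervals, for cholesterol biosynthesis (blue), metallothionein and acute phase (red) and interferon response (green) genes. Of each list only some members are drawn, and the 4 blue genes lie below 1 and the 4 red and 3 green genes above it.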

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

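The tests of a lone library, of the sex of control 4 and of nuclear transcripts were chosen only after the result was seen. A library was singled out where its gap to the nearest of the 4 libraries of its group was too large a part of the group's range by Dixon's test. This held in 18 of 52 groups tested. The chance rate of about 1 in 20 groups is for independent normal values and is no measure of this count, since in 7 of the 18 the other 3 libraries were at 0, where any value above 0 stands apart. Hepatocyte-like barcodes stood apart in control 2 (64.3%, others up to 4.26%) and HFHC 3 (72.1%, others 0%). LSEC-like cells (80.5%, others up to 1.35%) and vascular endothelial-like cells (15.4%, others up to 0.817%) stood apart in HFHC 4. So did its LEC-like cells (1.14%, others up to 0.117%), of which 0 of 7 carried at least 2 lymphatic markers. Neutrophil-like cells (38.2%, or 3 of 55 cells with clustering centred per sample) and mesothelial-like cells (30.9%) did so in control 1, and mesothelial-like cells (27.7%) in HFHC 1. Basophil-like cells stood apart in control 2 (1.83%) and HFHC 3 (3.62%), as did plasmacytoid dendritic-like cells (0.686% and 0.817%), and platelet-like cells in HFHC 3 (2.57%). Control 4 stood apart in LEC-like cells (39.4%), in cells with at least 2 lymphatic markers (46.8%), in cells with Xist (71.3%) and in cells with a Y-linked transcript (0%, others 20 to 21.4%). Tmem106c stood at 20.3 CPM in all cells of control 3 and at 11.3 to 11.7 in the other controls.

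LSEC-like cells passed the cell minimum in HFHC 4 alone among HFHC libraries, and 19 genes, Esm1, Cd36 and Wnt2 among them, passed the test there. The sex of control 4 is argued against for these genes alone. Their median absolute log2 fold change without that library was 97.0% of that with it (2.61 and 2.69), with 19 of 19 signs kept. The test had little room to fail, since control 4 held 76644 LSEC-like UMIs against 756159 in control 3. Unequal sampling of sinusoid zones stays open, since 14 of 16 pericentral genes were lower and 15 of 16 periportal genes higher in HFHC 4. For 17 of the 19 genes, all but Wnt2 and Cxcl9, the level lay outside the intervals of 3 zone groups of control 3 cells, but this excludes nothing, since the genes were picked for a difference from controls that include control 3, and 3 groups do not resolve rarer cells such as the cluster led by Esm1, Cxcl9 and Kcnj8 (208 cells of HFHC 4, 26 of control 3). Whether HFHC 4 may stand apart whatever its diet cannot be told apart from the diet, since with 1 of 4 choices of a lone library giving as many calls (control 2 alone gave 13) no share under 0.05 can be had.

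Hepatocyte-like barcodes filled control 2 and HFHC 3 although the sort was for endothelial cells, and they held few nuclear Malat1 transcripts (247 and 77.0 CPM). Loss of nuclear transcripts from the whole library is argued against, because Malat1 was at least 149.5 times as abundant in B-like cells (36953 and 29081 CPM). Droplets with free RNA alone stay open, since these barcodes held at least 12.7 times the hepatocyte transcript UMIs of B-like cells in the same library but 7 of the 25 transcripts counted are among the markers of their class. Hepatocyte fragments without a nucleus stay open as an untested source, and no biological explanation was tested.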

How the results depend on the processing

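The tests with barcode copies kept and with library sets were chosen only after the result was seen. Over the alternatives run, 132 values of the main results stayed within bounds, 20 moved, 13 changed direction or fell to 0 and 1 newly passed; of values of single genes 728 stayed, 113 lost the call, 34 moved and 13 changed direction. Where no reason is given, the cause was not tested, and settings with libraries named in brackets changed these as well. Esm1 passed in 15 of 15 LSEC settings, Kcne3 and Kcnj8 in 12 of 15, Cd36 and Cyp26b1 in 9 of 15, and Wnt2 and Hpgd in 7 of 15, all with their direction kept.

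Of genes past the test in LSEC-like cells, 19 in the main setting, there were 37 with DESeq2 size factors, 3 with DESeq2, 9 with at least 500 genes per cell, 8 without Scrublet doublets, 37 at Leiden resolution 2, 5 with clustering centred per sample (controls 3 and 4 against HFHC 4), 1 with barcode copies kept (4 controls against HFHC 3 and HFHC 4, 2142 genes tested) and 6 to 65 on leaving out 1 control. It was 13 without a filter on low counts and 21 with classes from marker expression (controls 2 and 3 against HFHC 4). Without scaling, the median of all genes in LSEC-like cells moved to −0.18 on the log2 scale. Of genes past the test in vascular endothelial-like cells, 20 in the main setting, there were 0 with DESeq2 (raw 10), 9 with no filter on low counts, 12 without Scrublet doublets, 0 with classes from marker expression (edgeR, raw 31, control 4 added) and 0 with a minimum of 5 cells (edgeR, raw 23, HFHC 3 added). Genes changed in all cells summed were 0, and 1 in only the 3 other libraries. Gene lists past camera in LSEC-like cells were 10, 0 with an estimated correlation, 0 with fry and 6 with barcode copies kept. Gene lists past camera in all cells summed were 18, 0 with an estimated correlation and 0 with fry.

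Log2 changes that turned sign were never past the test. Cdh5 in LSEC was 0.00365 with clustering centred per sample and −0.282 to 0.0173 on leaving out 1 control, Nrp2 in LSEC 0.0208 and, with classes from marker expression, 0.0316, Vcam1 in LSEC −0.92 with those classes and −0.39 to 1.86 on leaving out 1 control, and Cldn5 in LSEC −0.37 to 0.12 on leaving out 1 control. Cdh5 in vascular was −0.00498 with DESeq2 size factors, −0.0631 with at least 500 genes and −0.0911 with barcode copies kept, and Cd36 in vascular was 1.22 with classes from marker expression. The Pglyrp1 ratio in neutrophil-like cells was 0.896 with clustering centred per sample, which left 3 such cells in control 1.

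Shares of cells per class turned too. The LSEC-like difference of −16.1 was −6.01 with marker classes, −7.86 as percent of endothelial-like cells, 13.8 in only the 3 other libraries and −36.1 to 3.08 on leaving out 1 library, and the LEC-like difference −13.1 to 0.0248. Percents of endothelial-like cells leave out HFHC 1 and rest on 4 such cells in control 1, 1 in HFHC 2 and 10 in HFHC 3. For vascular endothelial-like cells 1.46 became 17.0 as percent of endothelial-like cells and −1.80 with marker classes. It was −1.67 in only the 5 barcode-sharing libraries and −2.33 to 2.81 on leaving out 1 library. For hepatocyte-like cells it was −9.04 in the 5 barcode-sharing and −2.13 in the 3 other libraries, and −17.6 to 16.0 on leaving out 1 library. The Kupffer-like difference of 10.4 became 6.24 with clustering centred per sample, 4.23 with barcode copies kept, 12.2 with marker classes, 13.8 in the 5 barcode-sharing and 0 in the 3 other libraries, and 6.76 to 13.8 on leaving out 1 library. The monocyte or macrophage-like difference of 2.84 was 0.571 with clustering centred per sample, 0.838 with barcode copies kept, 1.54 with marker classes, 0.0752 in the 3 other libraries and 1.89 to 3.96 on leaving out 1 library, the highest without HFHC 4 (unadjusted exact p = 0.0286, the smallest its 35 assignments allow).

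A replicate block called 0 genes in all cells (edgeR, raw 110), but the labels do not say that the numbers pair the mice. The correlation with the HFHC library of the same number was 0.498, −0.0809, −0.416 and 0.162, the highest for replicates 1 and 4 only. Control 2 was closest to HFHC 3 (0.830), both mostly hepatocyte-like, and control 3 to HFHC 4 (0.776), both mostly LSEC-like. These correlations thus go with the make-up of the libraries and cannot tell whether mice were paired. Not run were the block in single classes, LSEC-like cells without HFHC 4, and for vascular cells centred clustering, a minimum of 20 cells and leaving out a library. Tests of LEC-like and other classes were not run. Olr1 and Vegfc had too few counts to test in LSEC-like cells, where low depth and low expression were not told apart.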

Other observations

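The tests of shared barcodes and of other splits of the libraries were chosen only after the result was seen. Basophil-like and mesothelial-like cells gave further pairs of libraries, with no replicate check, that compare libraries and not diets. In basophil-like cells (16 in control 2, 31 in HFHC 3) the cytokine Osm stood at a ratio of 0.358 (counting interval 0.273 to 0.468), and the heat shock gene Hspa1a had 34 counts in HFHC 3 and 0 in control 2. In mesothelial-like cells (17 in control 1, 13 in HFHC 1) the metallothionein Mt2 stood at 5.11 (2.98 to 9.32). Classes from marker expression gave 15 mesothelial-like and 14 fibroblast-like cells in control 1 and 9 and 1 in HFHC 1, so a difference in make-up between these libraries is not excluded.

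LSEC-like cells of control 3 and HFHC 4 differed in further genes. The chemokine Ccl2 stood at a ratio of 14.7 (4.76 to 73.9), the matrix protein gene Ctgf at 10.2 (4.72 to 26.2), and Vcam1, an adhesion receptor for leukocytes, at 2.68 (1.84 to 3.98), where edgeR on the 3 controls gave Vcam1 a log2 fold change of 0.28 that did not pass. Ehd3, a gene of sinusoidal identity, stood at 0.438 (0.405 to 0.475). MHC class I genes were lower for 14 of 14 members (median log2 ratio −0.51, percentile 0.17 among random lists), but against all 3 controls 7 were higher and 7 lower (median −0.03, camera adjusted p = 0.976). In the pair, glycolysis genes had a median of 0.37 (percentile 99.99). In all cells summed, 16 of 16 measured genes of fatty acid oxidation were higher in the HFHC mean (median log2 0.45, camera adjusted p = 0.264).

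Barcodes recurred in 5 libraries, with 105 in more than 1 library and 28 in all 5. Chance reuse is argued against, because control 1 with HFHC 1 shared 496 times as many barcodes per pair of cells as control 3 with HFHC 4 (53 and 4 barcodes). Cells with the same barcode in different libraries were more alike than the median of other pairs in 99.54% of 216 pairs (median r 0.574 and 0.368 across genes, which are not independent replicates), a result consistent with reads carried over between libraries. The library with most UMIs held a median of 10.6 times those of the copy. No biological explanation was tested.

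For all cells summed, the diets gave 0 genes (edgeR, 54 at raw p under 0.05, DESeq2 0), so that all 35 splits of the 8 libraries into 4 and 4 reach that count by construction and their number decides nothing. The highest other split called 514 genes, with control 1, control 3, control 4 and HFHC 4 against the rest, and 2 splits called any. A split with so many genes points to a structure of the libraries, but it was singled out after its count was seen. Its sides follow the barcode-sharing division except for control 1, which is grouped with control 3, control 4 and HFHC 4. What sets its sides apart was not tested.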
